A study of Arabidopsis thaliana with 2 samples.

How the data were processed

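Biotin-labelled RNA from shoots of Arabidopsis thaliana Col-0 was hybridised to 2 Affymetrix ATH1 arrays, 1 from plants grown with NPA and 1 from plants grown with DMSO. Per the labels, plants grew at about 20 C with 16 h of light after at least 2 days of stratification, and both samples were at developmental stage 1.04. The groups were taken from the treatment named in the labels, and both samples carry replicate number 1. The deposited values are array signal intensity on a linear scale, 1 per probe set. The submitters' processing notes name MAS5 and GCOS, without versions, as the software behind the deposited intensity values. The mean of each array after trimming its lowest and highest signals was 100.0 in the control and 100.0 with NPA, so the arrays had been scaled to a common mean before deposit. Detection calls were not used here.

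The array holds 22810 probe sets, of which 64 are controls and 22746 were analysed. Probe sets were named through the array's annotation and the TAIR10.1 gene table, which was used for names only. Of the analysed probe sets, 13513 have 1 gene, 503 have several and 8730, or 38.4%, are unnamed here. Of the 13513, 13436 were matched to the gene table by gene identifier. No gene was named from a probe set with several genes. A gene was read from its brightest probe set with exactly 1 gene, which gave 13356 genes, of which 6809 were above the floor in both arrays.

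Signals below an array's 40th percentile, 28.3 in the control and 27.9 with NPA, were set to that floor. A gene was measured when at least 1 array was above its floor. The log2 ratio of NPA over control was then taken, and a difference with 1 array at the floor is a lower bound, written as at least so many fold. No test was run, because each group has 1 array, and genes were called by a size rule of 2-fold. The gene lists and the rule for named genes were fixed before the data were examined. The rule took the 10 largest ratios in each direction with both arrays above the floor, the 5 largest lower bounds in each direction, and from each list up to 4 measured members with the largest absolute log2 ratio and any member at 2-fold or beyond. Genes that fall outside this rule are said to have been chosen later. A list with at least 5 measured members was set against 10000 random lists of the same size, matched in 20 bins of mean signal, as a description of these arrays. Of 539 list members written by locus, 64 were named on the array and 45 measured. A further 1, the anthocyanin gene AT5MAT, was dropped because the name written for it did not match its symbol.

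The state of the arrays was read from control probe sets. The 18 probe sets of hybridisation spike-ins had a mean log2 ratio of -0.07 with an SD of 0.21 and a range from -0.61 to 0.20. The 27 bacterial control probe sets that were not spiked reached at most 15.7 in the control and 10.9 with NPA, below both floors. Their median was 4.75 in the control and 2.47 with NPA, so these lowest signals were lower on the NPA array. The ratio of 3' to 5' signal was 2.21 in the control and 1.66 with NPA for actin, 0.893 and 0.803 for GAPDH, and 1.85 and 1.64 for ubiquitin. Older probe set pairs gave 3.02 and 6.32 for actin, 2.08 and 1.45 for GAPDH, and 2.22 and 2.56 for ubiquitin. Over 12824 probe sets above the floor in both arrays, log2 signals correlated at r = 0.923 and rho = 0.897 across probe sets, which are not independent replicates, and the log2 ratio had an SD of 0.56. For 52 genes with at least 2 such probe sets, the log2 ratios of 1 gene's probe sets spanned a median of 0.25, and 3 of these genes spanned more than 1.

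The steps were tested on simulated arrays made from the control signals with the spread of the spike-ins, which holds no difference between plants. All 50 probe sets were recovered at each of the simulated log2 changes 1.5, -1.5, 2.5 and -2.5, and 0 of 13731 unchanged probe sets passed 2-fold. Changes were planted only in probe sets well above the floor, with a noise SD of 0.21 at every signal level. The real log2 ratios had an SD of 0.56, so the simulation checks the steps and gives no rate of false 2-fold calls. Of 100 random unchanged lists, 5 lay outside the middle 95%. Alternatives were median centring, quantile normalization, lowess centring with a span of 0.3, floors at the 25th and 55th percentile, no floor, the floor added to both signals, no probe sets shared between genes, the mean of a gene's probe sets, the mean in place of a list's median, size rules of 1.5-fold and 3-fold, and a rule of 3 local spreads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.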

Results

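Transcript signals were measured in shoots of Arabidopsis thaliana, ecotype Col-0, on 2 Affymetrix ATH1 arrays, 1 per group. One group of plants grew on medium with N-1-naphthylphthalamic acid (NPA), an inhibitor of polar auxin transport, and the other on medium with the same volume of its solvent DMSO. Shoots were taken at about 2 weeks, when the plants had about 6 rosette leaves. The labels give the NPA concentration as 10 uM in the notes of the treated sample and as 10 mM in the protocol shared by both samples, so the dose stays open. The median signal was 43.3 on the control array and 44.5 on the NPA array, and signals up to 28.3 and 27.9 were treated as at the floor. Each group had 1 array, so no difference given here has a replicate check, and the number of arrays limits the precision of every value.

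The comparison of NPA with DMSO asks which shoot transcripts differ when auxin transport is inhibited, in a series whose title names vascular overgrowth. Transcripts of anthocyanin synthesis, of the senescence-associated sugar transporter SAG29, of the expansin-like gene EXLB1 and of the auxin-conjugating enzyme gene GH3.3 were higher in the NPA array. DFR, which encodes dihydroflavonol reductase, had a signal of 84.8 in the control and 559 with NPA, and EXLB1 had 110 and 1074. GH3.3 had 29.5, close to the floor, and 98.9, and came under 2-fold with a higher floor. Transcripts of the methionine sulfoxide reductase MSRB6, the sugar transporter SWEET2 and the thionin THI2.2 were lower. MSRB6 had a signal of 519 in the control and 34.5 with NPA.

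Of 7753 named genes measured above the floor in at least 1 array, 291 were at least 2-fold higher with NPA and 165 at least 2-fold lower. Of these, 253 and 147 were above the floor in both arrays. At 4-fold or more there were 41 higher and 9 lower genes, and at 1.5-fold or more 869 and 822. Higher genes also outnumbered lower ones with the floor at the 25th percentile (421 and 297), at the 55th (205 and 112) and with the floor added to both signals (178 and 69), but not without a floor (1102 and 1340). Over all 14470 measured probe sets, named or not, 661 were at least 2-fold higher and 321 at least 2-fold lower.

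**Figure D1:**
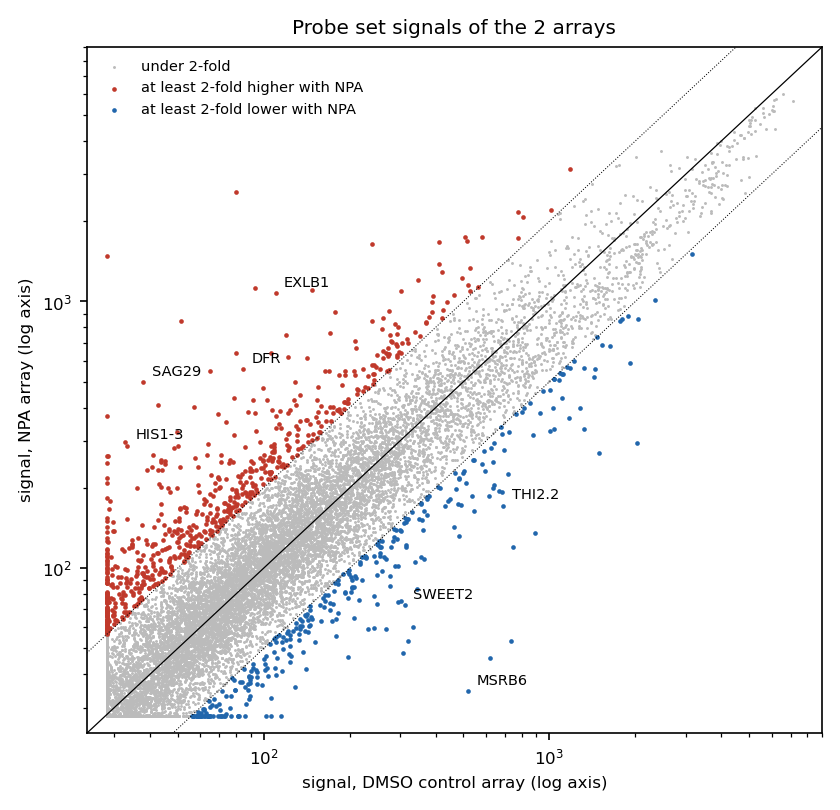
Signals of the 14470 measured probe sets in the DMSO control array (x, log axis) and the NPA array (y, log axis), with signals under an array's floor drawn at the floor. The solid line marks equal signals and the dotted lines 2-fold differences; 661 probe sets lie on or above the upper dotted line and 321 on or below the lower one.

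Among named genes above the floor in both arrays, AT2G37870 had the largest ratio in the higher direction, 16.4-fold, with signals of 51.5 and 846. SAG29, a sugar transporter of the SWEET family also known as SWEET15, was 13.1-fold higher with NPA, from 37.9 to 497. AT3G53980 was 12-fold higher, EXLB1 9.75-fold and the linker histone gene HIS1-3 8.65-fold. AT4G33550, AT1G80130, AT3G18280 and AT5G22460 were 8.43-fold, 7.44-fold, 6.88-fold and 6.49-fold higher, and DFR 6.59-fold. With the floor added to both signals, SAG29 was 7.96-fold higher, HIS1-3 5.15-fold and AT5G22460 4.25-fold. Among genes at the floor in the control array, AT5G37970 was at least 13.1-fold higher with NPA and AT4G14090 at least 7.71-fold. AT3G25290 was at least 5.46-fold higher, AT3G02480 at least 5.03-fold, and BHLH101, a transcription factor gene of the iron deficiency response, at least 4.56-fold. These bounds become lower as the floor is raised: at the 55th percentile they were 6.98-fold for AT5G37970, 4.11-fold for AT4G14090, 2.91-fold for AT3G25290, 2.68-fold for AT3G02480 and 2.43-fold for BHLH101.

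In the lower direction, MSRB6 was 15.0-fold lower with NPA and AT3G16670 13.4-fold. AT1G66100 had a signal of 2022 in the control and 294 with NPA, a 6.87-fold difference. AT5G44020, AT1G13650 and AT1G04040 were 6.58-fold, 6.42-fold and 5.54-fold lower. With the floor added to both signals, MSRB6 was 8.74-fold lower and AT3G16670 8.73-fold. SWEET2 was 4.29-fold lower, AT1G06830 4.07-fold, THI2.2 4.02-fold and AT1G33811 3.94-fold. Among genes at the floor in the NPA array, the defensin gene PDF1.2b was at least 3.79-fold lower, and its probe set can also bind transcripts of related genes. AT3G61100, AT3G49160, AT5G03120 and AT4G15660 were at least 3.07-fold, 2.92-fold, 2.91-fold and 2.48-fold lower. With the floor raised to the 55th percentile, these 5 genes at the NPA floor came under 2-fold.

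**Figure D2:**
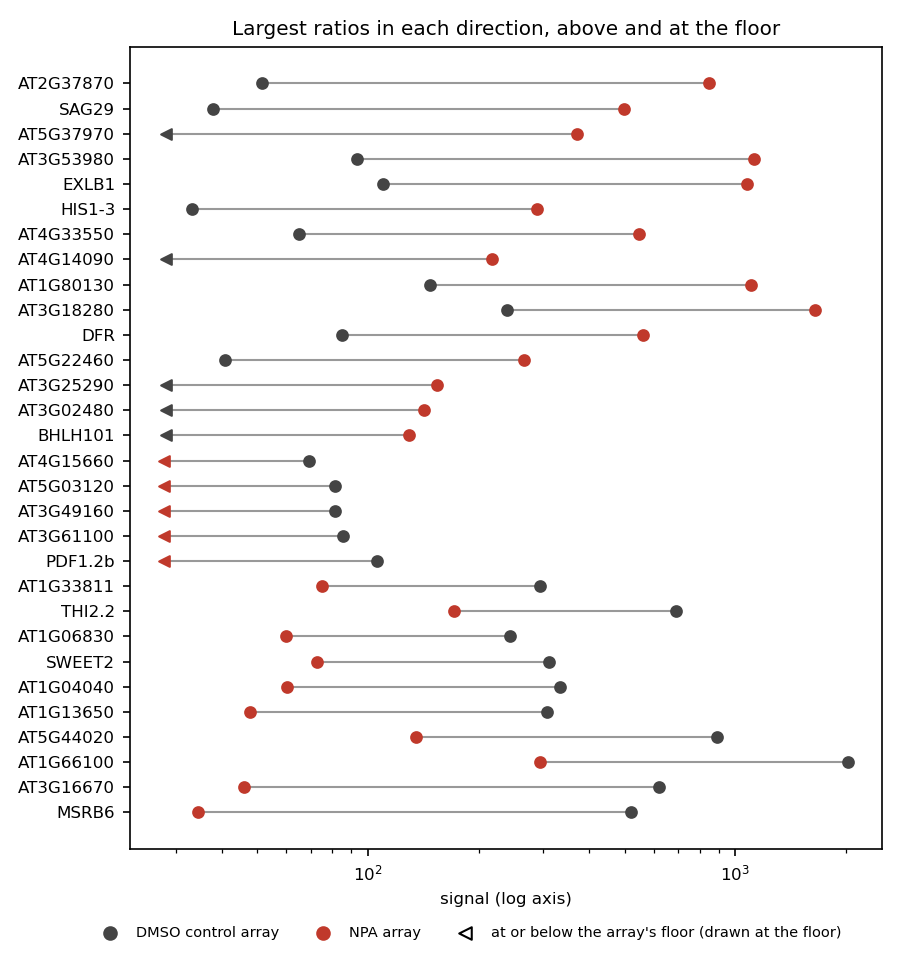
Signals (x, log axis) of 30 named genes, the 10 largest ratios in each direction above the floor in both arrays and the 5 largest lower bounds in each direction at the floor in 1 array, with the DMSO control array in grey and the NPA array in red. Unnamed probe sets are left out. Triangles mark signals at or below the array's floor, drawn at the floor, so that the distance to them is a lower bound; MSRB6 lies at 519 in the control and 34.5 with NPA.

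Of 39 gene lists written before the data were examined, 4 had at least 5 measured members, 22 had 1 to 4, and 13 had none. The expansin genes, a list that also holds expansin-like genes such as EXLB1, were the only one of the 4 lists whose median lay outside the middle 95% of random lists. Of 12 measured expansin genes, 3 were at least 2-fold higher with NPA and 0 at least 2-fold lower, with 8 above and 4 below a log2 ratio of 0. EXLB1 was 9.75-fold higher, EXPB3 2.53-fold and EXPA9 2.23-fold, while EXLA1 had a log2 ratio of -0.66. The list's median log2 ratio was 0.44, and 10 of 10000 random lists of equally bright genes had a median as high. That median lay between EXPA20, at the floor in the control, and EXLA2, whose control signal of 28.6 was close to the floor of 28.3. The median was 0.28 with the floor at the 25th percentile and 0.23 without a floor, where 117 and 186 of 10000 random lists were as high. With the floor at the 55th percentile 79 were as high, and with the floor added to both signals 110. In 9 of 9 alternative settings the median lay outside the middle 95% of random lists drawn under that setting, a check chosen after the data were seen. Some of these settings could hardly change the call. Median centring shifts the list and its random lists alike, and leaving out shared probe sets or averaging a gene's probe sets left the median at 0.44. EXPA9 came under 2-fold with the floor at the 55th percentile, at a log2 ratio of 0.78, and with the floor added to both signals, at 0.79.

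All 3 measured genes kept in the flavonoid and anthocyanin list were at least 2-fold higher with NPA. AT5MAT, dropped from that list over its name, is given among the other observations. DFR was 6.59-fold higher, and the glycosyltransferase gene UF3GT had signals of 44.0 and 232, a 5.28-fold difference. AT4G14090, listed as an anthocyanin glucosyltransferase, was at least 7.71-fold higher, a bound of 4.11-fold with the floor at the 55th percentile, and 4.8-fold higher with the floor added to both signals. With 3 measured members the list was not set against random lists.

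Few auxin-related genes were measured: 2 of 27 AUX/IAA genes, 4 of 26 GH3 and SAUR genes, all of them GH3, and 2 of 15 auxin synthesis genes. Most of the others had no named probe set here, and those measured went in different directions. GH3.3 was 3.36-fold higher with NPA, from a control signal of 29.5, close to the floor of 28.3. WES1, also known as GH3.5, was 2.09-fold higher, and both genes encode enzymes that conjugate auxin to amino acids. GH3.17 had a log2 ratio of -0.08, and GH3.9, at the floor with NPA, was at least 1.07-fold lower. IAA18, a repressor of auxin response, had a log2 ratio of -0.50, and IAA29 was at least 1.39-fold lower. Of the auxin synthesis genes, YUC2 had a log2 ratio of -0.61 and YUC6 was at least 1.44-fold higher. GH3.3 came under 2-fold with the floor at the 55th percentile, at a log2 ratio of 0.90, and WES1 with the floor added to both signals, at 0.91.

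Of 25 genes in the procambium and vascular patterning list, 4 were measured, too few to be set against random lists, and 0 reached 2-fold. All 4 had a log2 ratio above 0, at 0.71 for LHW, 0.59 for PHV, 0.40 for CLE44 and 0.17 for CLE41, and stayed above 0 under the 3 other scalings. The median of these genes stayed between 0.43 and 0.50 under those scalings, so the signs had little room to change. LHW encodes a transcription factor of vascular cell divisions, and CLE41 and CLE44 encode the peptide that maintains the procambium. Of 24 genes of the xylem secondary wall and autolysis, 1 was measured. This was the xylan synthesis gene GUT2, also known as IRX10, with a log2 ratio of 0.12. Of 17 lignin precursor genes 2 were measured: HCT had a log2 ratio of -0.48 and CCR2 was at least 1.08-fold higher. The phloem sucrose transporter gene SWEET11, the only 1 of 28 phloem genes measured, had a log2 ratio of -0.47.

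Genes of the shoot apex and leaf shape included 2 that were at least 2-fold lower. LAS, a regulator of axillary meristems, was 2.08-fold lower with NPA, and the leaf polarity gene YAB3 was 2.21-fold lower, whereas YAB5 had a log2 ratio of 0.34. ARR15, a response regulator of cytokinin signalling, was at least 2.14-fold lower. The gibberellin receptor gene GID1A was 2.1-fold higher, GID1C had a log2 ratio of 0.24, and GID1B was at least 1.2-fold higher. LAS, ARR15 and GID1A came under 2-fold with the floor at the 55th percentile, and LAS, GID1A and YAB3 with the floor added to both signals, YAB3 at a log2 ratio of -0.87.

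The pectin methylesterase genes PME61 and PMEPCRF were 2.07-fold and 1.93-fold higher with NPA, and PME61 came just under 2-fold after quantile normalization, at a log2 ratio of 0.99, and with the floor added to both signals, at 0.82. Of the peroxidase genes, PRX52 was at least 1.53-fold higher, AT5G64120 had a log2 ratio of 0.58, and AT2G41480 was at least 1.01-fold higher. Of 5 measured xyloglucan endotransglucosylase/hydrolase genes, 0 reached 2-fold, and the list's median of -0.16 lay inside the range of random lists. That median was -0.39 with the floor at the 25th percentile and -0.52 without a floor, both inside the range of random lists drawn under the same setting. EXGT-A3 had a log2 ratio of -0.33, XTH32 0.24 and XTH16 -0.16, and XTH18 was at least 1.24-fold lower. XTH18 passed 2-fold with lower floors, at a log2 ratio of -1.46 with the floor at the 25th percentile and -1.58 without a floor, so the count of 0 holds for the main floor. Of 7 tubulin genes 0 reached 2-fold, with TUB6 at 0.69, TUB1 at 0.64, TUA6 at 0.20 and TUA1 at -0.36, and the median of 0.16 also lay inside that range. COB, which orients cellulose deposition, had a log2 ratio of -0.37 and EXPA8 -0.61.

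All 5 measured photosynthesis genes had log2 ratios below 0, with a median of -0.27 that turned to 0.10 after lowess centring and was matched by random lists of equally bright genes. SBPASE had the lowest log2 ratio, -0.77, and PRK had -0.50. LHCB4.1 and LHCB4.2 had -0.27 and -0.21, and both turned positive after lowess centring, LHCB4.2 also after quantile normalization. Of 3 measured histone genes, HIS1-3 was 8.65-fold higher, while HON4 and HTB2 had log2 ratios of 0.25 and -0.48. The jasmonate-responsive thionin gene THI2.1 had a log2 ratio of 0.88, and PDF1.2 was at least 1.07-fold lower. The clock gene GI had a log2 ratio of 0.84, and WRKY53, at the floor in the control and barely above it with NPA, is given no fold.

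Markers of other tissues were also read. The root-expressed genes PYK10 and EXPA18 had log2 ratios of -0.52 and -0.37, and the stomatal genes FMA and STOMAGEN had -0.44 and -0.79. None of the flower markers had a named probe set here, so they could not be read. The 4 reference genes ranged from -0.11 for AT4G26410 to 0.46 for PEX4, with 0.14 for AT2G28390 and 0.15 for AT4G34270.

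**Figure D3:**
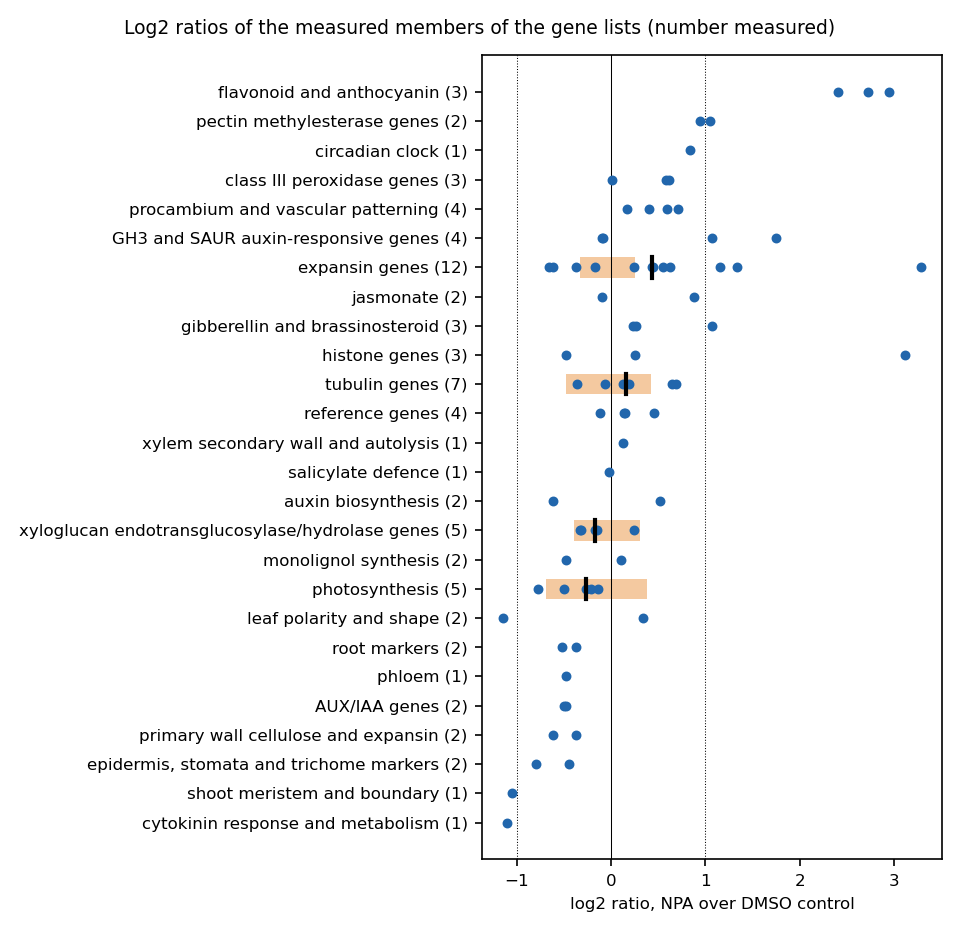
Log2 ratios of NPA over DMSO control (x) for the measured members of the 26 lists with at least 1, with the number measured in brackets. Each point is a gene, dotted lines mark 2-fold, and for the 4 lists with at least 5 members the bar is the middle 95% of 10000 random lists and the black line the list's median, which lies outside the bar for the expansin genes.

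Much of the array carries no gene name here. Of the 661 probe sets at least 2-fold higher with NPA, 355 were unnamed, as were 147 of the 321 lower ones. The 2 unnamed probe sets furthest in the higher direction were 32.3-fold higher, from 79.9 to 2581, and at least 52.2-fold higher, and the 2 furthest in the lower direction were 13.7-fold and 6.2-fold lower. The lists with no measured member were those of auxin transport, auxin response factors and receptors, xylem regulators, cell cycle, ethylene, xenobiotic detoxification, senescence, flower markers, ribosomal proteins, laccases, fasciclin-like arabinogalactan proteins, heat shock proteins and aquaporins, which were not analysed here. Of these, auxin transport (1 gene), xenobiotic detoxification (3) and laccases (1) had named genes, all at the floor in both arrays. The others had no named gene.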

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

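The counts of all probe sets and the organelle lists were added after the data were seen. No paired analysis was possible because the groups share only 1 replicate number, and with 1 array per group no array could be left out. The causes of the shifts given here were not tested, except that a stricter or looser size rule changes a count by construction. Of 106 values of counts and lists under the alternatives, 75 moved little, 31 moved and 0 reversed the direction of a list that stood apart. A count, or a list that did not stand apart, was not called reversed. The photosynthesis median nonetheless turned positive after lowess centring, and the mitochondrial one with the floor at the 55th percentile. Lower genes outnumbered higher ones without a floor. With the floor at the 55th percentile, 205 genes were higher and 112 lower. Without a floor, 1102 genes were higher and 1340 lower at 2-fold, and 1976 and 2000 probe sets, with list medians of 0.23 for expansins and -0.52 for xyloglucan endotransglucosylase/hydrolases. The share of higher genes was then 45.1%, against 63.8% with the floor. With the floor at the 25th percentile, 297 genes and 517 probe sets were lower, the expansin median was 0.28 and the xyloglucan endotransglucosylase/hydrolase median -0.39. At the 55th percentile the expansin median was 0.62 and the mitochondrial one 0.16. With the floor added to both signals, 178 genes were higher and 69 lower, and 409 and 147 probe sets. A 1.5-fold rule gave 869 higher and 822 lower genes and 1881 and 1524 probe sets, a 3-fold rule 75 and 18 genes and 170 and 49 probe sets, and a rule of 3 local spreads 120 and 39 genes and 224 and 71 probe sets. The plastid median was -0.27 after quantile normalization and -0.21 after lowess centring, and the photosynthesis median was 0.10 after lowess centring. Of 793 values of the 90 named genes, 733 moved little and 60 moved, and 13 of 40 genes at 2-fold came under it in at least 1 alternative, while 5 of 50 under it reached it both with the floor at the 25th percentile and without one: XTH18, IAA29, PRX52, PDF1.2 and CCR2, all at the floor in 1 array. Median, quantile and lowess scaling moved 0 named genes by more than the local spread, although after lowess centring PRK was at -0.16 against -0.50 and LHCB4.1 and LHCB4.2 were above 0.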

Other observations

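The genes, families and lists in this part were chosen after their values were seen, as were the tests on mitochondrial genes and on the raised floor and the rule that a bound must be passed by more than a value's 95% interval. The neighbouring paralogs MSRB5 and MSRB6 went in opposite directions, with MSRB5 3.06-fold higher with NPA (113 to 347) and MSRB6 15.0-fold lower (519 to 34.5). Genes of the SWEET sugar transporter family also went both ways: SWEET13 was 2.39-fold and SWEET4 2.37-fold higher, while SWEET2 was 4.29-fold and SWEET16 2.19-fold lower. The 12 measured genes with a SWEET symbol leave out SAG29 (SWEET15, 13.1-fold higher). Their median log2 ratio was -0.12, inside the middle 95% of random lists. Genes of starch metabolism at 2-fold or more included APL3, 4.18-fold higher, APL4, at least 3.28-fold, DPE1, 3.57-fold, and PWD at AT4G24450, 3.26-fold. A starch list made without the genes that prompted it had 1 measured member, SBE2.2, with a log2 ratio of 0.29, so these genes stand as single values. A first version of that list held the 4 genes that prompted it and was dropped for that reason. The anthocyanin acyltransferase gene AT5MAT was at least 2.16-fold higher, and it had been written into the flavonoid list before the data were examined. The vacuolar protease genes BETA-VPE and GAMMA-VPE were 4.62-fold and 3.00-fold higher, SIM, a cell cycle inhibitor gene of trichomes, was 2.94-fold higher, and TRY, which represses trichomes, was at least 2.31-fold lower.

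Of 29 families of genes with a shared symbol and at least 5 measured members, 7 had a median outside the middle 95% of random lists. By chance 1.45 would be expected if genes varied independently, which was not checked. The 7 are not all separate from the lists described elsewhere, since all members of RPL and RPS are plastid-encoded and all 6 of EXPA are in the expansin list. All 8 measured ATG genes, of autophagy, had log2 ratios above 0, with a median of 0.55 and 0.84 for ATG8B. Of 8 aldehyde dehydrogenase genes 7 were above 0, with a median of 0.75 and 1.34 for ALDH7B4. The VPS genes, of endosomal sorting, had a median of 0.46, the EXPA expansins 0.49 and the CYP genes 0.58, the last with CYP71, a cyclophilin, among cytochrome P450 genes. The plastid RPL and RPS genes had medians of -0.64 and -0.56. The directions of these medians held under the 3 other scalings, although RPS had 1 of 8 genes above 0 after quantile or lowess scaling and a median of -0.36 after lowess, and CYP had 7 of 12 genes above 0 after quantile normalization against 8 as deposited.

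Of 68 measured plastid-encoded genes, 64 had log2 ratios below 0, with a median of -0.38, and 17 of 10000 equally bright random lists of genes outside the organelles were as low; after lowess centring 52 of 68 were below 0. The choice of that background followed a first run on all genes, in which the list also stood apart. The random lists and the intervals over genes treat genes as independent, which was not checked, so they may be too narrow. A brightness-dependent difference between the arrays stays open: the median after lowess centring was -0.21, with a 95% interval over genes from -0.30 to -0.13 that spans the bound of random lists at -0.17. A lower yield of transcripts without a long poly(A) tail, shared by both organelles, was not decided. The 10 mitochondrial genes had a median of -0.10, above the range of -0.58 to -0.24 for medians of equally many plastid genes. Its interval, from -0.33 to 0.16, still reaches that range. The mitochondrial median was -0.01 without shared probe sets and 0.16 with the floor at the 55th percentile. Ribosomal protein and polymerase genes of the plastid had a median of -0.58, NADH dehydrogenase-like genes -0.48 and photosystem, cytochrome, ATP synthase and rbcL genes -0.28, and a response of the plastid to NPA is among the open explanations, untested here.

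More probe sets were higher than lower at 2-fold, by a ratio of 2.06. The excess depended on the size rule, with 1881 higher and 1524 lower at 1.5-fold and 170 and 49 at 3-fold. At the 2-fold rule the values argue only against the choice among these scalings as the whole cause. The lowest ratio over 3 other scalings was 1.75, with an exact binomial 95% interval from 1.54 to 2.00 that covers counting only. The arrays came already scaled to a common mean, and these scalings left the median log2 ratio of probe sets between -0.04 and 0. A scaling error that all of them share was therefore not tested. The tables also argue against the probe sets nearest the floor as the whole cause at 2-fold. With the floor at the 55th percentile the ratio was 2.07 (475 higher and 229 lower), with an interval from 1.77 to 2.44. A wider part of dim probe sets stays open, as the ratio among the brightest 3206 was 1.52 (143 and 94), with an interval from 1.16 to 2.00. Without a floor the excess was absent (1976 and 2000), and a biological excess of higher transcripts was not tested.

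Several genes known to respond to cold and dehydration were higher with NPA: COR15A 5.75-fold, OSM34 6.16-fold, HIS1-3 8.65-fold, COR47 2.17-fold and LTI30 at least 3.12-fold. One hypothesis is that a class-wide water-deficit response may lie behind them. Of 17 other water-deficit and LEA genes named on the array, 13 were at the floor in both arrays, and the 4 measured had a median log2 ratio of 0.27, too few for a comparison with random lists, so the hypothesis stays undecided.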
